A study of Saccharomyces pastorianus with 12 samples.

How the data were processed

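Messenger RNA was measured in SpIB1 and SpIB2, a pair of lager yeast strains of Saccharomyces pastorianus, the hybrid species used for cold beer fermentation. Per the labels' protocols, both strains fermented brewing wort at 16 °C for 5 days, RNA was extracted with hot phenol, only RNA with an integrity number above 8 was used, and libraries were made from polyA RNA at a commercial provider. The labels give 4 groups (each strain on day 2 and on day 5) with 3 libraries per group, 12 in all. The labels do not say whether the replicates came from separate fermentations, so p-values measure only the spread between these samples, which may be technical in part.

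The authors deposited read counts per gene copy, as whole numbers that are not normalised, in 1 table per library. Trimmomatic 0.38, STAR 2.7.3a, HTSeq 0.11.1 and edgeR 3.34.0 are named in the submitters' processing notes, without roles. The genome build and annotation, the strand setting and the treatment of reads that match several copies are not given in the sources used here. Each table lists 11312 gene copies. Of these, 9289 carry a gene symbol, mostly with a copy number behind it (4738 distinct symbols, 3963 of them with 2 copies, 530 with 1 copy and 245 with 3 or more), and 2023 carry a locus tag only. The files do not say which copy comes from which parent species, and no coordinates were used. Copies of a symbol, and near-identical members of the MAL, IMA, HXT, PAU and FLO families, can share reads, so the values of single copies are uncertain and sums per symbol are given beside the leading maltose genes.

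In 35 cells, each in a different gene copy, the deposited text held the strain name SpIB2 in place of digits. The string 790 was the only 3-digit string absent from all readable counts. These 35 copies were left out of the tests, and an alternative chosen after seeing the data put 790 back. Library totals over the readable copies ran from 5180189 to 8020151 reads. A floor of 3 reads corresponds to 0.374 to 0.579 CPM (reads scaled to a common library total) per library, and intervals and floors cover counting error only. In all 12 libraries, 67 copies had 0 reads.

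Counts were tested with edgeR 4.0.16 in R 4.3.3. Copies were kept by edgeR's expression filter (10659 copies), libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to all 12 libraries with 1 coefficient per group (8 residual degrees of freedom). CPM values in the text are TMM-scaled means ± SD of n = 3 libraries unless stated otherwise. There were 5 contrasts: the strain difference (SpIB2 minus SpIB1) on day 2 and on day 5, the day effect (day 5 minus day 2) in SpIB1 and in SpIB2, and the difference of the day effects. A copy was called at a Benjamini-Hochberg adjusted p under 0.05, and the standard error of a log2 fold change was taken from the quasi-likelihood F statistic. A copy without reads in 1 group is given as a lower bound against 3 reads over that group.

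Before the data were examined, 24 gene lists were fixed from gene names. One list, of mitochondrially encoded genes, had 0 members in the tables, and 23 lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, which makes 115 tests over the contrasts. Beside each call stands the p from camera with a correlation estimated for that list, where 1 of the 61 calls held, and counts are also given adjusted over the list alone. Among the 61 called lists, the median, the mean and the test had the same sign. Among the 54 that were not called, they differed in sign in 14. The genes named follow a rule fixed at the same time: copies of the maltose list; per contrast up to 10 copies each way with a symbol, the largest change, a mean of at least 10 CPM in the higher group and libraries that did not overlap between the groups (chance gives 10 percent for 3 against 3); and up to 4 called members per list. Only part of what the rule names is printed.

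The fit was tested on simulated counts with the real means and library sizes and 200 of 10659 copies changed. At 4-fold it recovered 92, 86, 98, 87 and 46 percent in the order of the contrasts above. At 2-fold it recovered 17, 13, 12, 19 and 3 percent. Wrong calls made up 4.39, 2.94, 4.35, 4.50 and 7.55 percent of all calls. With so few copies changed the adjusted threshold is stricter than where many copies are called. All these shares hold for the simulated setting only, not for the real spread. That spread differed between the strains (biological coefficient of variation 0.191 in SpIB1 and 0.369 in SpIB2, each fitted alone).

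The alternatives fixed beforehand were median-ratio size factors, library totals without TMM, no expression filter, a mean count of at least 50, DESeq2 1.42.0, limma voom, a 2-fold threshold, the replicate number as a block, only the 6 libraries compared, and each library left out in turn, and for the lists an estimated correlation and fry. DESeq2 used a local regression in place of its parametric trend. Added after seeing the data were the restored cells, the removal of 2 SpIB2 libraries that stood apart, counts summed per symbol, and limma voom with library weights per strain. Centring the strain difference per chromosome, and the results per chromosome or parental genome, were not run because the copies could not be placed on a genome.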

Results

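The question behind the series is which genes underlie the different use of maltose and maltotriose by 2 lager yeast strains. RNA of both was sequenced on days 2 and 5, with 3 libraries per group. The first principal component held 62.4% of the variance and separated the strains, and the second held 19.6% and separated the days in SpIB2. Replicates of SpIB1 correlated at a Pearson r of 0.966 to 0.988 (log2 CPM across copies). In SpIB2, day 2 replicate 3 (r = 0.897 and 0.906 with its replicates) and day 5 replicate 1 (r = 0.922 and 0.914) stood apart, against 0.951 and 0.970 for the remaining pair of each day. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 8.02 to 113), so no pair was taken for repeated deposits of 1 library.

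**Figure D1:**
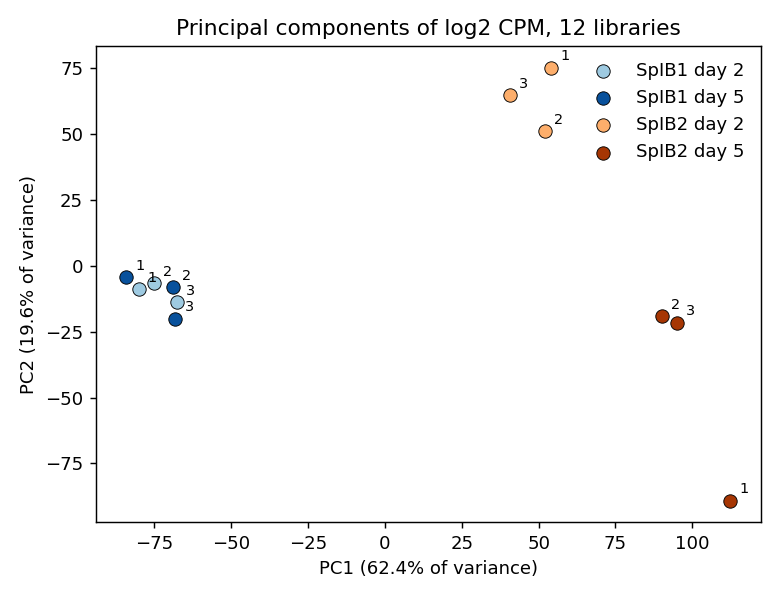
Principal components of log2 CPM for the 12 libraries, each point 1 library numbered by its replicate. The horizontal axis holds 62.4% and the vertical axis 19.6% of the variance; SpIB1 libraries of both days lie together, and SpIB2 libraries lie apart from them and from each other by day, with day 5 replicate 1 farthest out.

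The first comparison asked how the strains differed on day 2. Among the maltose genes, SpIB2 had more transcript of the maltase copy MAL32_1, which splits maltose inside the cell, at 7347 ± 1631 CPM against 2731 ± 631 CPM in SpIB1 (log2 fold change 1.43 ± 0.37 SE, edgeR adjusted p = 0.00922). It also had more of the maltose permease copy MAL31_2, at 989 ± 213 against 431 ± 115 CPM (log2 fold change 1.20 ± 0.36, edgeR adjusted p = 0.0185), and of the MAL activator copies MAL33_1 (1.33 ± 0.24) and MAL33_2 (1.91 ± 0.23). SpIB1 had more of MAL11, the broad alpha-glucoside transporter that also carries maltotriose. MAL11_1 stood at 62.5 ± 7.23 CPM in SpIB1 and 21 ± 5.17 CPM in SpIB2 (log2 fold change -1.57 ± 0.24, edgeR adjusted p = 0.000292). MAL11_2 stood at 78.3 ± 16.7 and 17.7 ± 3.78 CPM (log2 fold change -2.14 ± 0.27, edgeR adjusted p = 5.08e-05). The alpha-glucoside permease MPH3 was also lower in SpIB2 (-1.39 ± 0.28). The scarce copy MAL11_3 went the other way, at 7.58 ± 6.37 CPM in SpIB2 and 2.6 ± 0.33 CPM in SpIB1 (log2 fold change 1.55 ± 0.56, edgeR adjusted p = 0.0456).

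Of the 40 copies in the list of maltose and maltotriose genes, 9 were higher and 6 lower in SpIB2 (9 and 7 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.995). With counts summed over copies, MAL11 was lower in SpIB2 (log2 fold change -1.63 ± 0.27, edgeR adjusted p = 0.000978) and MAL32 was higher (1.39 ± 0.34, edgeR adjusted p = 0.0108). MAL33 was higher as well (1.19 ± 0.28, edgeR adjusted p = 0.00744), and MAL31 did not pass the test (0.73 ± 0.33, edgeR adjusted p = 0.112). The MAL11_3 call ended in 9 of 17 alternatives (edgeR, DESeq2 and limma adjusted p from 0.0212 to 0.391), among them the fits without any 1 of the SpIB1 day 2 libraries (replicate 1, 2 or 3) and without SpIB2 day 2 replicate 3, where its log2 fold change was 0.58. That of MAL31_2 ended in 3 (edgeR, DESeq2 and limma adjusted p from 0.00105 to 0.0983), namely without SpIB1 day 2 replicate 1 or 2 or SpIB2 day 2 replicate 1. Without SpIB1 day 2 replicate 1 the MAL32_1 call ended too (edgeR, DESeq2 and limma adjusted p over the alternatives 7.19e-06 to 0.0579). The 9 higher maltose copies numbered 2 (with 7 lower) and 5 without SpIB1 day 2 replicate 1 or 2.

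**Figure D2:**
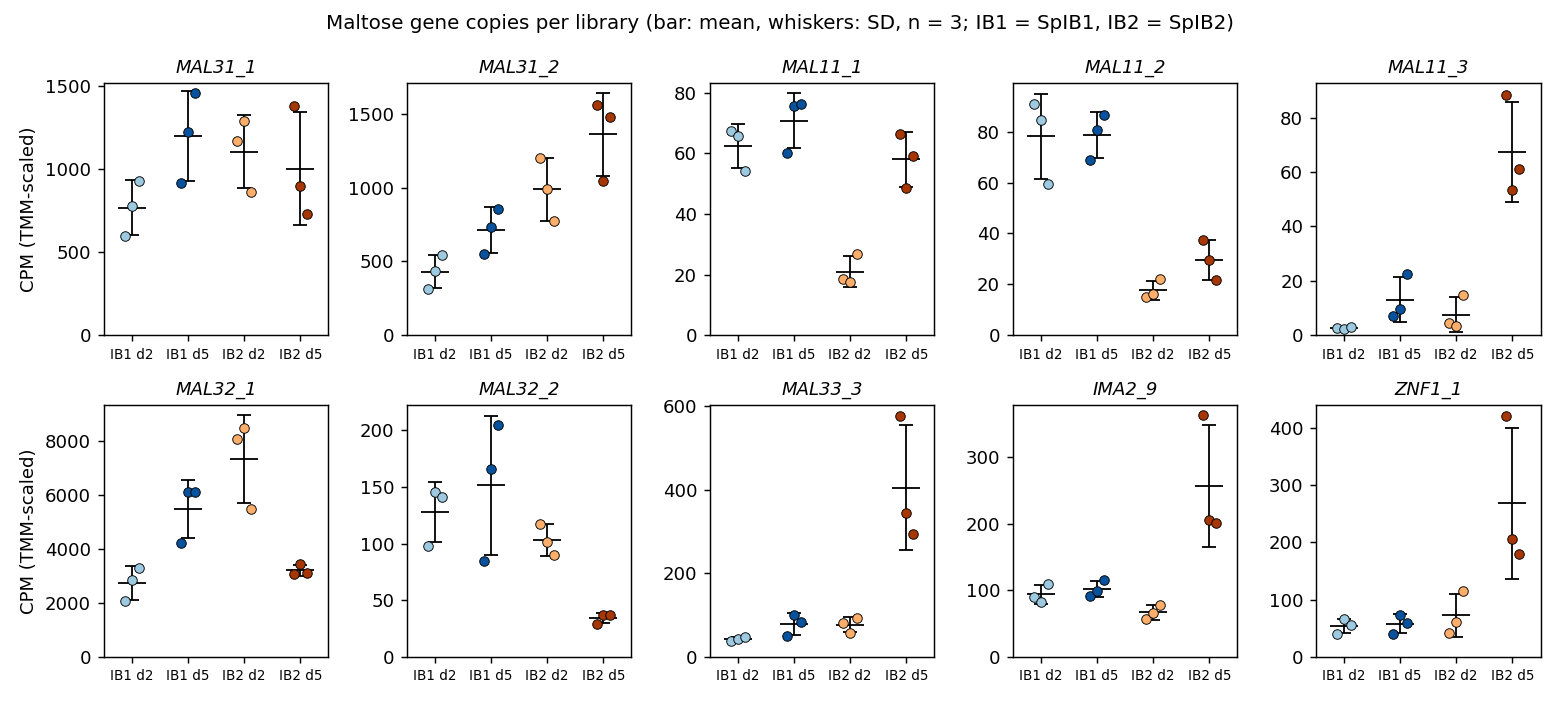
TMM-scaled CPM of 10 maltose gene copies in each library, by strain and day (IB1 is SpIB1, IB2 is SpIB2, d2 and d5 are the days); points are libraries, bars are means and whiskers SD of n = 3, each axis starting at 0. MAL32_1 was 2731 ± 631 CPM in SpIB1 and 7347 ± 1631 CPM in SpIB2 on day 2, and MAL11_1 and MAL11_2 were lower in SpIB2 on that day.

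Beyond sugar use, on day 2, of the 249 cytosolic ribosomal proteins 117 copies were higher in SpIB2 and 0 lower, such as RPL29_2, 5.41-fold, and RPS14A_3, 4.47-fold. Cytosolic ribosomal proteins had 131 copies higher and 1 lower adjusted over the list alone with a median log2 fold change of 0.98 (camera adjusted p = 3.10e-07, adjusted p = 0.993 with an estimated correlation). The 117 higher ribosomal protein copies numbered 57 and 72 without SpIB1 day 2 replicate 1 or 3, 76 without SpIB2 day 2 replicate 1 and 71 with library totals. In ribosome biogenesis 39 of 119 were lower and 4 higher; the helicase SPB4_1 was 3.25-fold and NOP9_1 3.62-fold lower. In ribosome biogenesis, 4 were higher and 39 lower adjusted over the list alone (camera adjusted p = 5.54e-05, adjusted p = 0.993 with an estimated correlation). The 39 lower ribosome biogenesis copies numbered 20 and 23 without SpIB1 day 2 replicate 1 or 2, 20, 25 and 64 without SpIB2 day 2 replicate 1, 2 or 3 and 81 without the 2 SpIB2 libraries that stood apart. In the TCA cycle and respiratory chain, 36 of 88 copies were higher and 1 lower. Counts for the TCA cycle and respiratory chain adjusted over the list alone were 39 higher and 2 lower (camera adjusted p = 0.000724, adjusted p = 0.993 with an estimated correlation). The 36 higher TCA cycle and respiratory copies numbered 23 and 23 without SpIB1 day 2 replicate 1 or 2. Among markers of dividing cells, 28 of 61 were higher and 3 lower, with the cell-cycle regulator SWI5_2 6.33-fold and the histone HTA1_2 10.8-fold higher. Dividing cells had 30 copies higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00328, adjusted p = 0.993 with an estimated correlation). The 28 higher dividing-cell copies numbered 18 without SpIB1 day 2 replicate 1. Amino acid synthesis had 29 of 102 copies higher and 4 lower, such as SER1_2 (1.52 ± 0.24) and HOM6_1 (1.43 ± 0.24). In amino acid synthesis, 27 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0342, adjusted p = 0.993 with an estimated correlation). The amino acid synthesis list lost its call without SpIB1 day 2 replicate 1 or 3 or SpIB2 day 2 replicate 2 (camera adjusted p = 0.0545 to 0.101).

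The list of zinc, iron, phosphate and thiamine starvation had 25 of 68 copies lower and 5 higher. Counts for starvation genes adjusted over the list alone were 6 higher and 25 lower (camera adjusted p = 0.00155, adjusted p = 0.993 with an estimated correlation). Among its iron uptake genes, the iron permease copy FTR1_2 stood at 732 ± 163 CPM in SpIB1 and 11.1 ± 8.33 CPM in SpIB2 (log2 fold change -6.04 ± 0.6, edgeR adjusted p = 4.71e-06). The iron oxidase copy FET3_2 stood at 536 ± 242 and 15.6 ± 7.58 CPM, and the siderophore transporter SIT1_2 was 7.06-fold lower. Gluconeogenesis and the glyoxylate cycle had 20 of 50 lower and 5 higher, with the carriers SFC1_1 and CRC1_1 5.14-fold and 5.62-fold lower. Gluconeogenesis had 5 copies higher and 22 lower adjusted over the list alone (camera adjusted p = 0.00865, adjusted p = 0.993 with an estimated correlation). Anaerobic and low-oxygen genes had 12 of 44 lower and 5 higher; the seripauperins PAU17_2 and PAU5_2 were 30.7-fold and 17.1-fold lower. In low-oxygen genes, 5 were higher and 12 lower adjusted over the list alone (camera adjusted p = 0.0293, adjusted p = 0.993 with an estimated correlation). The low-oxygen list lost its call without SpIB2 day 2 replicate 3 or the 2 SpIB2 libraries that stood apart (camera adjusted p = 0.126 to 0.144). The flocculin FLO5_1 stood at 628 ± 129.8 CPM in SpIB1 and 16.5 ± 1.97 CPM in SpIB2, and the stress gene GRE1 was 17.5-fold lower. UIP3 had 2 reads over the SpIB2 libraries, a ratio of 357 with a counting interval of 98.7 to 2957. The lists of glycolysis and ethanol formation (16 higher, 3 lower of 44; camera adjusted p = 0.0667) and hexose transport and glucose sensing (5 higher, 16 lower of 51; camera adjusted p = 0.0986) were not called. Adjusted over the list alone they had 20 and 4, and 5 and 16, higher and lower. The 16 higher glycolysis copies numbered 6 and 9 without SpIB1 day 2 replicate 1 or 2 and 9 without SpIB2 day 2 replicate 1.

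Some copies had reads in SpIB2 and 0 in every SpIB1 library. On day 2 these included the vacuolar aminopeptidase APE1_2 at 1037 ± 338 CPM, at least 7073-fold higher against a floor of 3 reads over the SpIB1 group, the mevalonate pathway copy MVD1_1 (at least 6129-fold), the succinate dehydrogenase copy SDH3_2 (at least 536-fold) and HAP4_2, an activator of respiratory genes (at least 2145-fold). The partner copy MVD1_2 went the opposite way, at 2772 ± 575 CPM in SpIB1 and 561 ± 432 CPM in SpIB2.

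**Figure D3:**
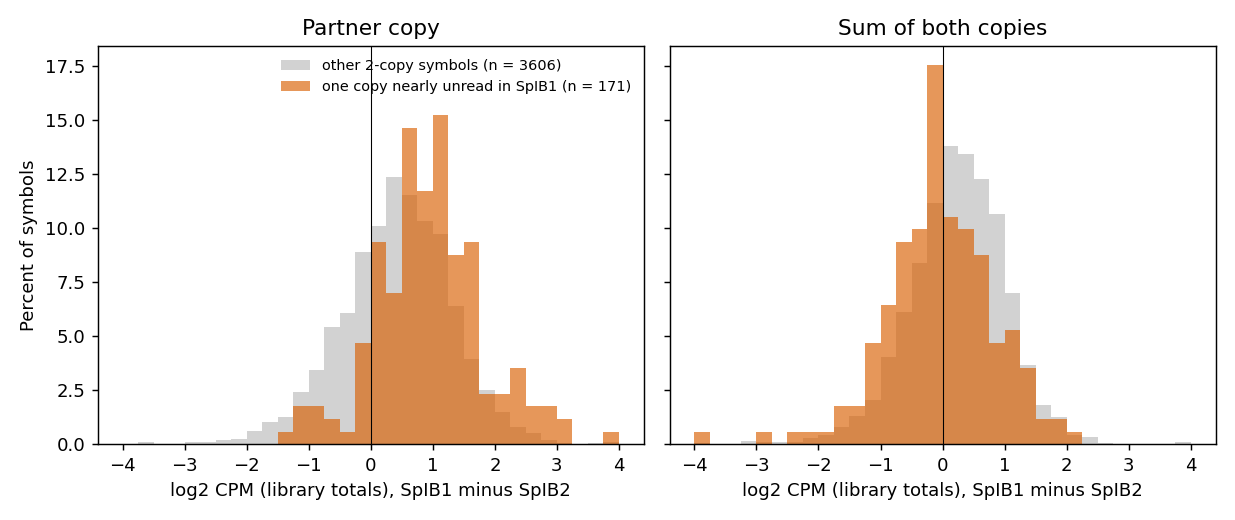
Distribution over symbols of the log2 CPM ratio, SpIB1 minus SpIB2 with library totals as the scale (horizontal axes) and percent of symbols (vertical axis), for the partner copy (left) and the sum of both copies (right). Orange are 171 symbols with 1 copy nearly unread in SpIB1 (at most 3 reads over 6 libraries), whose partner copies had a median of 0.93, and grey are 3606 other 2-copy symbols, with a median of 0.45.

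In all, edgeR called 2055 copies higher and 1707 lower in SpIB2 on day 2 at an adjusted p under 0.05 (1596 and 1160 also at least 2-fold), of 10659 tested. Without SpIB1 day 2 replicate 1 the counts were 1257 and 1077. Ergosterol synthesis was not called on day 2 (4 higher, 8 lower of 53; 2 and 3 adjusted over the list alone; camera adjusted p = 0.0985). The 8 lower ergosterol copies numbered 3, 3 and 4 without SpIB1 day 2 replicate 1, 2 or 3, 2, 4 and 15 without SpIB2 day 2 replicate 1, 2 or 3 and 29 without the 2 SpIB2 libraries that stood apart.

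The second comparison asked the same on day 5. SpIB2 then had more transcript of several MAL regulator copies and less of the maltase copies MAL32_2 and MAL62. The activator copies MAL63 and MAL33_3 were 6.26-fold and 5.19-fold higher, at 40.6 ± 9.79 against 6.44 ± 0.388 CPM (edgeR adjusted p = 2.17e-06) and 404 ± 149.8 against 77.9 ± 25.9 CPM (edgeR adjusted p = 9.66e-05). The zinc-cluster factor ZNF1_1 was 4.65-fold higher. The maltase copies MAL32_2 and MAL62 were 4.41-fold and 3.75-fold lower, at 34.3 ± 4.46 against 152 ± 61.3 CPM and 44.6 ± 7.33 against 167 ± 61 CPM. The most abundant maltase copy MAL32_1 stood at 3206 ± 199.8 against 5482 ± 1081 CPM and did not pass the test (log2 fold change -0.77 ± 0.37, edgeR adjusted p = 0.0847). Among transporters, MAL11_2 was lower (-1.42 ± 0.27), MAL11_3 higher (2.36 ± 0.49, from 13 ± 8.27 to 67.5 ± 18.4 CPM) and MAL31_2 higher (0.94 ± 0.35, edgeR adjusted p = 0.036) in SpIB2. Summed over copies, MAL11 no longer differed detectably (log2 fold change -0.14 ± 0.26, edgeR adjusted p = 0.659), nor did MAL31 (0.21 ± 0.33, edgeR adjusted p = 0.597). MAL33 was higher (1.91 ± 0.28, edgeR adjusted p = 0.000128) and MAL32 lower (-0.86 ± 0.34, edgeR adjusted p = 0.0452).

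Of the 40 maltose and maltotriose genes, 15 were higher and 5 lower on day 5 (15 and 5 adjusted over the list alone). Camera did not call the list (camera adjusted p = 0.338, adjusted p = 0.859 with an estimated correlation), but fry called it higher (fry adjusted p = 0.0264). The 15 higher maltose copies numbered 7 (with 15 lower) with library totals (list median -0.24 against 0.51). Library totals and DESeq2 called MAL32_1 lower (edgeR, DESeq2 and limma adjusted p over the 17 alternatives 0.00306 to 0.172), and MAL31_2 lost its call in 9 of 17 alternatives (edgeR, DESeq2 and limma adjusted p from 0.00489 to 0.727), among them the fits without any 1 of the SpIB1 day 5 libraries or without SpIB2 day 5 replicate 1 or 3.

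In the general stress response on day 5, 44 of 65 copies were higher and 1 lower, with the heat shock protein HSP12_2 at 5909 ± 1646 against 199.5 ± 41.9 CPM (log2 fold change 4.89 ± 0.46, edgeR adjusted p = 1.79e-06), the cell wall protein SPI1_2 44.5-fold and GRE3_2 12.3-fold higher. Counts for the general stress response adjusted over the list alone were 45 higher and 2 lower (camera adjusted p = 1.39e-07, adjusted p = 0.77 with an estimated correlation). In trehalose and glycogen, 33 of 43 were higher and 2 lower, with the trehalose phosphate synthase TPS1_2 15.7-fold and the trehalase NTH2_2 4.23-fold higher. Trehalose and glycogen had 33 copies higher and 2 lower adjusted over the list alone (camera adjusted p = 6.78e-06, adjusted p = 0.77 with an estimated correlation). The TCA cycle and respiratory chain had 59 of 88 higher and 0 lower. In the TCA cycle and respiratory chain, 59 were higher and 0 lower adjusted over the list alone (camera adjusted p = 2.55e-07, adjusted p = 0.77 with an estimated correlation). The 59 higher TCA cycle and respiratory copies numbered 31 with library totals. Anaerobic and low-oxygen genes had 24 of 44 higher and 0 lower, such as SUT1_2 (3.30 ± 0.41) and the mannoprotein TIR1_2 (2.96 ± 0.44). Counts for low-oxygen genes adjusted over the list alone were 24 higher and 0 lower (camera adjusted p = 0.00157, adjusted p = 0.77 with an estimated correlation). The 24 higher low-oxygen copies numbered 14 (with 4 lower) with library totals. Autophagy and vacuolar proteases had 27 of 54 higher and 3 lower, such as ATG18_2, 5.92-fold, and the carboxypeptidase CPS1_2, 10.9-fold. Autophagy had 27 copies higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00424, adjusted p = 0.77 with an estimated correlation). The 27 higher autophagy copies numbered 13 (with 9 lower) with library totals (list median 0.02 against 0.87). Flocculation and cell wall genes had 18 of 38 higher and 8 lower, although the flocculin FLO5_1 was 30.9-fold lower. In flocculation and cell wall genes, 19 were higher and 8 lower adjusted over the list alone (camera adjusted p = 0.0397, adjusted p = 0.77 with an estimated correlation). The 18 higher flocculation and cell wall copies numbered 9 (with 11 lower) with library totals (list median 0.09 against 0.90). The flocculation and cell wall list lost its call without SpIB1 day 5 replicate 2 or SpIB2 day 5 replicate 1 (camera adjusted p = 0.0628 to 0.0789).

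Ribosome biogenesis was lower in SpIB2 in 95 of 119 copies and higher in 3, with MAK16_1 9.39-fold and SPB4_1 7.92-fold lower. Counts for ribosome biogenesis adjusted over the list alone were 3 higher and 96 lower (camera adjusted p = 6.11e-12, adjusted p = 0.77 with an estimated correlation). Cytosolic ribosomal proteins were lower in 130 of 249 and higher in 4, with RPL8B_3 5.65-fold and RPS0 4.62-fold lower. Cytosolic ribosomal proteins had 4 copies higher and 129 lower adjusted over the list alone (camera adjusted p = 4.23e-09, adjusted p = 0.776 with an estimated correlation). The 130 lower ribosomal protein copies numbered 86 without SpIB1 day 5 replicate 1 and 199 with library totals. Nitrogen catabolite repression genes, which serve the use of poorer nitrogen sources, were lower in 39 of 80 and higher in 12. The general amino acid permease GAP1_1 stood at 47 ± 17.1 against 769 ± 102 CPM, the arginase CAR1_1 was 13.1-fold lower, and UGA2_2, of GABA breakdown, 16.7-fold higher. In nitrogen genes, 13 were higher and 40 lower adjusted over the list alone (camera adjusted p = 0.00311, adjusted p = 0.77 with an estimated correlation). The 12 higher nitrogen copies numbered 7 without SpIB1 day 5 replicate 3 and 4 with library totals. Amino acid synthesis was lower in 53 of 102 and higher in 18, with ARO1_1 4.67-fold lower. Counts for amino acid synthesis adjusted over the list alone were 19 higher and 53 lower (camera adjusted p = 0.0107, adjusted p = 0.77 with an estimated correlation). The 18 higher amino acid synthesis copies numbered 6 with library totals. Glycolysis and ethanol formation was lower in 18 of 44 and higher in 5, with PFK1_2 4.61-fold and PDC6_1 9.06-fold lower. Glycolysis had 5 copies higher and 18 lower adjusted over the list alone (camera adjusted p = 0.0397, adjusted p = 0.806 with an estimated correlation). The 18 lower glycolysis copies numbered 11 without SpIB1 day 5 replicate 3 and 28 with library totals. The glycolysis list lost its call without SpIB1 day 5 replicate 2 or 3 or SpIB2 day 5 replicate 1 or the 2 SpIB2 libraries that stood apart (camera adjusted p = 0.0539 to 0.12). The list of zinc, iron, phosphate and thiamine starvation was not called on day 5 (15 higher, 22 lower of 68; 15 and 22 adjusted over the list alone; camera adjusted p = 0.109). The 22 lower starvation copies numbered 39 (with 7 higher) with library totals. Among its iron uptake copies, FTR1_1 was 27.4 ± 5.37 against 903 ± 388 CPM and SIT1_2 11.3-fold lower, and outside the list the ferric reductase FRE4_1 was 36.1-fold lower. The urea transporter DUR3_1 was 24.5-fold and the glycerophosphoinositol transporter GIT1_1 75.9-fold lower. HAP4_2 and the calcineurin regulator RCN1_2, both at 0 reads in SpIB1, were at least 31478-fold and 8279.5-fold higher. These bounds hold for single copies, and no sums are given. Loss of a copy in SpIB1 and reads counted on another copy were not told apart. Copies unread in SpIB1 can count as higher in lists, and no list was tested without them. HAP4_2 varied between the SpIB2 libraries (4158 ± 4184 CPM).

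On day 5 edgeR called 3191 copies higher and 2824 lower in SpIB2 at an adjusted p under 0.05 (2629 and 2076 also at least 2-fold). The share called higher was 53.1% with TMM and 23.6% with library totals alone, under which the median copy shifted by -0.75 on the log2 scale, so all changes on this day are relative to the TMM scale. Ergosterol synthesis was not called on day 5 (8 higher, 14 lower of 53; 8 and 14 adjusted over the list alone; camera adjusted p = 0.452). The 14 lower ergosterol copies numbered 8 without SpIB1 day 5 replicate 1, 9 without SpIB2 day 5 replicate 3, 27 without the 2 SpIB2 libraries that stood apart and 29 (with 3 higher) with library totals. Across copies, the strain differences on the 2 days correlated (Pearson r = 0.79, Spearman rho = 0.46; copies are not independent replicates). In SpIB2, 1172 copies were higher on both days and 1034 lower on both, where independent lists would share 615 and 452.

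**Figure D4:**
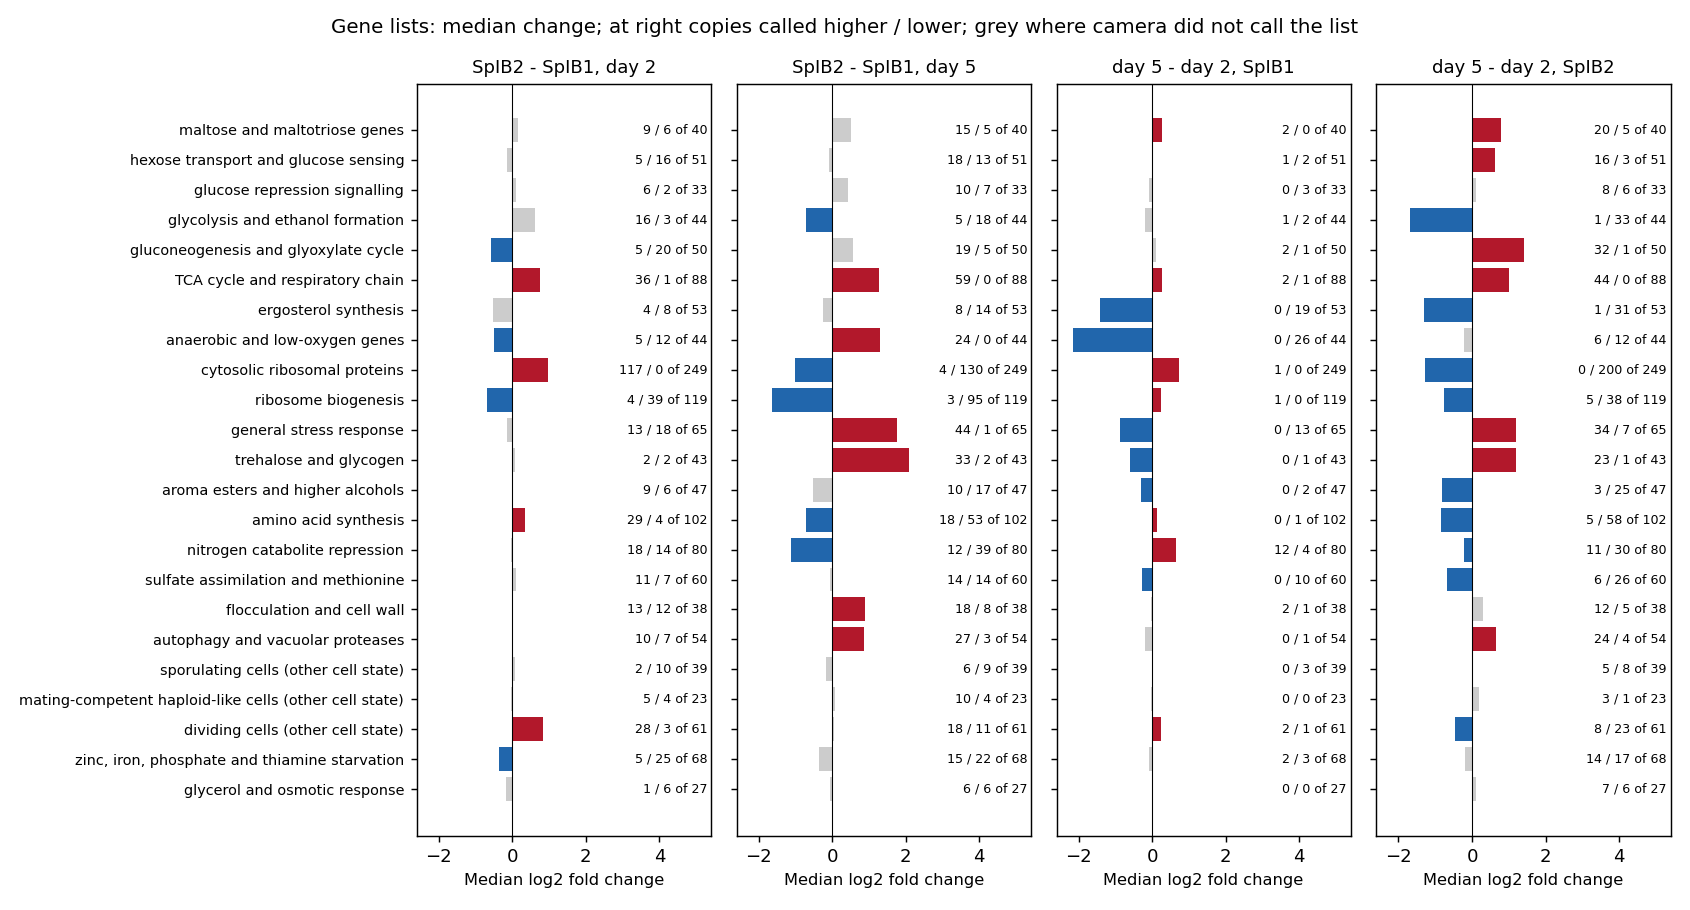
Median log2 fold change of each gene list in 4 contrasts (horizontal axis), coloured where camera called the list at a preset correlation and grey where it did not; the numbers at the right give copies called higher and lower of those measured. In SpIB2 minus SpIB1, cytosolic ribosomal proteins had 117 copies higher on day 2 and 130 lower on day 5; with library totals the median turned sign in 3, 5, 6 and 5 lists in the order of the contrasts, none of them called.

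The third comparison followed SpIB1 from day 2 to day 5. Of the 44 anaerobic and low-oxygen genes, 26 copies fell and 0 rose. In low-oxygen genes, 0 were higher and 31 lower adjusted over the list alone with a median log2 fold change of -2.14 (camera adjusted p = 1.18e-49, adjusted p = 0.0139 with an estimated correlation). The 26 lower low-oxygen copies numbered 17 without SpIB1 day 5 replicate 2. TIR1_2 fell from 2572 ± 524 to 76 ± 28.4 CPM (log2 fold change -5.08 ± 0.48, edgeR adjusted p = 9.07e-05), TIR1_1 from 3847 ± 797 to 198 ± 125 CPM, PAU17_1 by 32.2-fold and the hypoxic translation factor ANB1_2 by 15.5-fold. Ergosterol synthesis fell in 19 of 53 copies and rose in 0, such as ERG3_2, from 839.6 ± 52.3 to 113 ± 50.2 CPM, ERG6_1 (-2.69 ± 0.45) and ERG24_1 (-2.21 ± 0.34). The ERG6_1 call ended without SpIB1 day 5 replicate 2 or 3 (edgeR, DESeq2 and limma adjusted p over the alternatives 6.30e-08 to 0.0517). Counts for ergosterol synthesis adjusted over the list alone were 0 higher and 41 lower (camera adjusted p = 3.64e-32, adjusted p = 0.204 with an estimated correlation). The 19 lower ergosterol copies numbered 8, 9 and 10 without SpIB1 day 2 replicate 1, 2 or 3, 2 and 2 without SpIB1 day 5 replicate 2 or 3, 45 without the 2 SpIB2 libraries that stood apart and 12 with library totals.

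The general stress response fell in 13 of 65 copies and rose in 0, led by HSP12_1, 13.2-fold, and YGP1_2, 7.01-fold. The general stress response had 0 copies higher and 24 lower adjusted over the list alone (camera adjusted p = 7.35e-13, adjusted p = 0.205 with an estimated correlation). The 13 lower stress copies numbered 8 without SpIB1 day 2 replicate 3, 7, 5 and 8 without SpIB1 day 5 replicate 1, 2 or 3 and 28 (with 3 higher) without the 2 SpIB2 libraries that stood apart. Sulfate assimilation and methionine fell in 10 of 60 and rose in 0, with the sulfate permease SUL2_2 6.19-fold and MET16_1 4.51-fold lower. In sulfate assimilation and methionine, 0 were higher and 20 lower adjusted over the list alone (camera adjusted p = 6.27e-06, adjusted p = 0.204 with an estimated correlation). The 10 lower sulfate copies numbered 5, 3 and 4 without SpIB1 day 2 replicate 1, 2 or 3, 3 and 3 without SpIB1 day 5 replicate 2 or 3, 23 without the 2 SpIB2 libraries that stood apart and 5 with library totals (list median -0.01 against -0.26). Nitrogen catabolite repression genes rose in 12 of 80 and fell in 4. DUR3_1 rose from 277 ± 148 to 1428 ± 634 CPM and the repressor DAL80_1 by 5.73-fold, while UGA1_2 fell by 11.7-fold and UGA2_2 by 5.02-fold. Counts for nitrogen genes adjusted over the list alone were 22 higher and 5 lower (camera adjusted p = 5.75e-05, adjusted p = 0.647 with an estimated correlation). The 12 higher nitrogen copies numbered 2 (with 4 lower), 5 and 4 without SpIB1 day 2 replicate 1, 2 or 3, 6, 4 and 3 without SpIB1 day 5 replicate 1, 2 or 3 and 31 without the 2 SpIB2 libraries that stood apart. The oligopeptide transporter OPT2 rose 11.9-fold, GIT1_1 9.13-fold and the cell wall gene SCW10_1 7.61-fold. Among maltose and maltotriose genes 2 of 40 rose and 0 fell, namely MAL11_3 (2.32 ± 0.55) and MAL33_2 (0.89 ± 0.23). MAL32_1 went from 2731 ± 631 to 5482 ± 1081 CPM without passing the test (log2 fold change 1.01 ± 0.37, edgeR adjusted p = 0.156). MAL32_1 was called higher on day 5 in 4 of 17 alternatives, namely SpIB1 fitted alone, DESeq2, limma voom with library weights per strain, and without the 2 SpIB2 libraries that stood apart (edgeR, DESeq2 and limma adjusted p over the alternatives 0.0089 to 0.466). Maltose and maltotriose genes had 4 copies higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00122, adjusted p = 0.614 with an estimated correlation). The 2 higher maltose copies numbered 0, 1 and 0 without SpIB1 day 2 replicate 1, 2 or 3, 0 and 0 without SpIB1 day 5 replicate 2 or 3 and 8 without the 2 SpIB2 libraries that stood apart. Aroma genes fell in 2 of 47 copies, ARO10_2 (-3.31 ± 0.53) and ATF2_2 (-1.71 ± 0.28), with camera adjusted p = 0.012, adjusted p = 0.614 with an estimated correlation. The ATF2_2 call ended without SpIB1 day 5 replicate 2 (edgeR, DESeq2 and limma adjusted p over the alternatives 1.16e-08 to 0.0523). The 2 lower aroma copies numbered 1 without SpIB1 day 5 replicate 2 and 9 without the 2 SpIB2 libraries that stood apart. The aroma list lost its call without SpIB1 day 2 replicate 2 or SpIB1 day 5 replicate 2 (camera adjusted p = 0.0678 to 0.069). In cytosolic ribosomal proteins 1 of 249 copies, RPL7B_1 (1.26 ± 0.25), rose, and the list median was 0.73 (camera adjusted p = 4.41e-22, adjusted p = 0.689 with an estimated correlation). In place of 1 higher ribosomal protein copy there were 0 and 0 without SpIB1 day 2 replicate 2 or 3 and 122 without the 2 SpIB2 libraries that stood apart. The calls of DUR3_1, MAL11_3 and MAL33_2 ended in 8, 6 and 8 of 17 alternatives (edgeR, DESeq2 and limma adjusted p up to 0.177, 0.164 and 0.229), among them each fit without 1 of the SpIB1 libraries, except that the MAL copies kept theirs without day 5 replicate 1.

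Camera also called 5 lists with few called members in SpIB1. The TCA cycle and respiratory chain (2 higher, 1 lower of 88; camera adjusted p = 0.00131, adjusted p = 0.75 with an estimated correlation) and ribosome biogenesis (1 and 0 of 119; camera adjusted p = 0.00131, adjusted p = 0.75 with an estimated correlation) lay above other genes. So did amino acid synthesis (0 and 1 of 102; camera adjusted p = 0.0164, adjusted p = 0.74 with an estimated correlation) and dividing cells (2 and 1 of 61; camera adjusted p = 0.0443, adjusted p = 0.75 with an estimated correlation), and trehalose and glycogen lay below (0 and 1 of 43; camera adjusted p = 0.000523, adjusted p = 0.75 with an estimated correlation). Adjusted over the list alone, these 5 had 3 and 2, 1 and 0, 0 and 1, 5 and 2, and 0 and 1 copies higher and lower, aroma genes 0 and 3, and ribosomal proteins 1 and 0. Without SpIB1 day 5 replicate 2 these 5 lists had 0 called copies, and leaving out any other SpIB1 library left no TCA cycle copy higher and no trehalose and glycogen copy lower. Without SpIB1 day 5 replicate 1, the dividing-cell list had 3 copies higher and the ribosome biogenesis median turned to -0.0469. With library totals, 8 TCA cycle copies were higher and 0 lower, and 2 trehalose and glycogen copies were higher and 0 lower. Without the 2 SpIB2 libraries that stood apart, 24 TCA cycle, 8 ribosome biogenesis, 11 amino acid synthesis and 11 dividing-cell copies were higher and 12 trehalose and glycogen copies lower. The ribosome biogenesis list lost its call without SpIB1 day 2 replicate 3 or SpIB1 day 5 replicate 1 (camera adjusted p = 0.285 to 0.891). The amino acid synthesis list lost its call without SpIB1 day 2 replicate 1 or 3 or SpIB1 day 5 replicate 1 (camera adjusted p = 0.0624 to 0.105). The dividing-cell list lost its call without SpIB1 day 2 replicate 1 or 3 or SpIB1 day 5 replicate 2 (camera adjusted p = 0.11 to 0.35). The trehalose and glycogen list lost its call without SpIB1 day 5 replicate 1 (camera adjusted p = 0.105).

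In SpIB1 edgeR called 92 copies higher and 278 lower on day 5 than on day 2 at an adjusted p under 0.05 (88 and 259 at least 2-fold), a count that depends on the spread shared with SpIB2. With the 6 SpIB1 libraries fitted alone edgeR called 1070 higher and 1134 lower, DESeq2 called 463 and 660, and limma voom with library weights per strain 988 and 1279. The 370 calls were all among the 2204 of the fit on SpIB1 alone, in the same direction. Without the 2 SpIB2 libraries that stood apart, edgeR called 766 higher and 993 lower. With library totals 51.2% of calls were higher, against 24.9% with TMM, and the median copy shifted by 0.27. Leaving out day 2 replicate 1, 2 or 3 of SpIB1 gave 20, 31 and 24 copies higher and 132, 143 and 122 lower, and leaving out day 5 replicate 2 or 3 gave 21 and 27 higher and 66 and 76 lower.

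The fourth comparison followed SpIB2 over the same days. In glycolysis and ethanol formation 33 of 44 copies fell and 1 rose. The enolase ENO2 fell from 2696 ± 791 to 387 ± 35.8 CPM (log2 fold change -2.80 ± 0.4, edgeR adjusted p = 0.000212), the pyruvate decarboxylase PDC1_2 by 5.98-fold and PFK1_2 by 4.08-fold. In glycolysis, 2 were higher and 33 lower adjusted over the list alone (camera adjusted p = 7.26e-10, adjusted p = 0.446 with an estimated correlation). In gluconeogenesis and the glyoxylate cycle 32 of 50 rose and 1 fell, with the regulator CAT8_1 17.5-fold, the acetate transporter ADY2 14.9-fold and FBP1_2 6.07-fold higher. Counts for gluconeogenesis adjusted over the list alone were 33 higher and 1 lower (camera adjusted p = 9.10e-09, adjusted p = 0.446 with an estimated correlation). The TCA cycle and respiratory chain rose in 44 of 88 and fell in 0, such as NDE2_2 (3.18 ± 0.46) and QCR8_1 (2.55 ± 0.38). The TCA cycle and respiratory chain had 45 copies higher and 0 lower adjusted over the list alone (camera adjusted p = 2.97e-07, adjusted p = 0.497 with an estimated correlation). The 44 higher TCA cycle and respiratory copies numbered 25 without SpIB2 day 2 replicate 1, 25 without SpIB2 day 5 replicate 1 and 24 with library totals. Trehalose and glycogen rose in 23 of 43 and fell in 1, with the trehalase ATH1_2 11.1-fold and GAC1_2 10.8-fold higher. In trehalose and glycogen, 24 were higher and 1 lower adjusted over the list alone (camera adjusted p = 8.67e-06, adjusted p = 0.497 with an estimated correlation).

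Maltose and maltotriose genes rose in 20 of 40 copies and fell in 5 in SpIB2. Counts for maltose and maltotriose genes adjusted over the list alone were 22 higher and 5 lower (camera adjusted p = 0.00118, adjusted p = 0.497 with an estimated correlation). The 20 higher maltose copies numbered 10 with library totals. The activators MAL63 and MAL33_3 rose 4.67-fold and 5.25-fold, ZNF1_1 3.7-fold, the isomaltase copies IMA2_6 and IMA2_9 4.05-fold and 3.84-fold, and the transporter copies MAL11_1 and MAL11_3 2.75-fold and 8.76-fold. The maltase copies fell: MAL32_1 from 7347 ± 1631 to 3206 ± 199.8 CPM (log2 fold change -1.20 ± 0.37, edgeR adjusted p = 0.0179), MAL32_2 by 2.99-fold and MAL62 by 2.74-fold. The maltose permease copy MAL31_2 stood at 989 ± 213 and 1362 ± 279 CPM (log2 fold change 0.46 ± 0.35, edgeR adjusted p = 0.297). The MAL32_1 call ended in 4 of 17 alternatives (edgeR, DESeq2 and limma adjusted p from 0.000436 to 0.0971): SpIB2 fitted alone, library weights per strain, and without SpIB2 day 2 replicate 1 or 2.

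Among the copies with the largest rise in SpIB2, the hexose transporter HXT5_2 rose from 6.38 ± 2.54 to 2062 ± 1848 CPM, SPG4_1 from 6.66 ± 3.13 to 1419.8 ± 305 CPM (log2 fold change 7.74 ± 0.51, edgeR adjusted p = 3.78e-06), SPG5_2 70.9-fold, and BOP2_2 101-fold. The membrane heat shock protein HSP30 rose from 56.9 ± 24.7 to 5964 ± 3951 CPM. The general stress response rose in 34 of 65 and fell in 7, autophagy and vacuolar proteases in 24 and 4 of 54, with ATG39_2 11-fold and CPS1_2 9.8-fold higher, and hexose transport and glucose sensing in 16 and 3 of 51. Counts for hexose transport and glucose sensing adjusted over the list alone were 15 higher and 2 lower (camera adjusted p = 0.00471, adjusted p = 0.497 with an estimated correlation). The 16 higher hexose transport copies numbered 10 without SpIB2 day 5 replicate 1 and 10 (with 7 lower) with library totals (list median 0.02 against 0.63). In autophagy, 24 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.000879, adjusted p = 0.497 with an estimated correlation). The 24 higher autophagy copies numbered 13 (with 7 lower) with library totals (list median 0.18 against 0.64). The general stress response had 34 copies higher and 7 lower adjusted over the list alone (camera adjusted p = 1.61e-07, adjusted p = 0.446 with an estimated correlation). The starvation list was not called in SpIB2 (14 higher, 17 lower of 68, 15 and 17 adjusted over the list alone, camera adjusted p = 0.674), with a median of -0.18 and a mean of 0.06. The 17 lower starvation copies numbered 10 (with 14 higher) without SpIB2 day 5 replicate 3. The 14 higher starvation copies numbered 9 without SpIB2 day 2 replicate 1 and 9 with library totals.

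Ribosomal protein copies fell in 200 of 249 and rose in 0, such as RPS0 (-1.68 ± 0.29) and RPL8B_3 (-1.73 ± 0.32), and ribosome biogenesis fell in 38 of 119 and rose in 5. In ribosome biogenesis, 5 were higher and 25 lower adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.764 with an estimated correlation). The 38 lower ribosome biogenesis copies numbered 7 (with 11 higher) without SpIB2 day 2 replicate 3, 16 and 15 without SpIB2 day 5 replicate 1 or 3, 2 (with 14 higher) without the 2 SpIB2 libraries that stood apart and 62 (with 2 higher) with library totals. The ribosome biogenesis list lost its call without SpIB2 day 2 replicate 3 or the 2 SpIB2 libraries that stood apart (camera adjusted p = 0.314 to 0.882). Cytosolic ribosomal proteins had 0 copies higher and 220 lower adjusted over the list alone (camera adjusted p = 4.28e-19, adjusted p = 0.497 with an estimated correlation). The 200 lower ribosomal protein copies numbered 128 without SpIB2 day 2 replicate 1 and 127 without the 2 SpIB2 libraries that stood apart. Ergosterol synthesis fell in 31 of 53 and rose in 1, with ERG6_1 10.2-fold and ERG3_2 9.23-fold lower. Outside the list, the acetyl-CoA synthetase ACS2_1 was 9.13-fold lower. Counts for ergosterol synthesis adjusted over the list alone were 2 higher and 32 lower (camera adjusted p = 4.29e-08, adjusted p = 0.497 with an estimated correlation). Amino acid synthesis fell in 58 of 102 and rose in 5, with LYS21_1 and HOM6_1 3.86-fold and 3.39-fold lower and the glutamate dehydrogenase GDH3_1 19.7-fold higher. Amino acid synthesis had 6 copies higher and 61 lower adjusted over the list alone (camera adjusted p = 6.30e-07, adjusted p = 0.446 with an estimated correlation). Sulfate assimilation and methionine fell in 26 of 60 and rose in 6, with MET6_2 5.15-fold and MET17_1 3.57-fold lower. In sulfate assimilation and methionine, 6 were higher and 27 lower adjusted over the list alone (camera adjusted p = 0.00225, adjusted p = 0.446 with an estimated correlation). Aroma esters and higher alcohols fell in 25 of 47 and rose in 3; the alcohol acetyltransferase ATF2_1 fell 8.62-fold and the transaminase BAT2_2 rose 4.4-fold. Counts for aroma esters and higher alcohols adjusted over the list alone were 3 higher and 25 lower (camera adjusted p = 0.00125, adjusted p = 0.446 with an estimated correlation). Nitrogen catabolite repression genes fell in 30 of 80 and rose in 11, with UGA1_2 26.3-fold and the permease UGA4_1 13.5-fold lower. Nitrogen genes had 12 copies higher and 30 lower adjusted over the list alone (camera adjusted p = 0.0131, adjusted p = 0.617 with an estimated correlation). The 11 higher nitrogen copies numbered 4 without SpIB2 day 2 replicate 1, 7 without SpIB2 day 5 replicate 1, 6 without the 2 SpIB2 libraries that stood apart and 3 with library totals. The nitrogen list lost its call without SpIB2 day 2 replicate 3 or SpIB2 day 5 replicate 2 or 3 (camera adjusted p = 0.062 to 0.108). Markers of dividing cells fell in 23 of 61 and rose in 8, such as CDC5_1, from 4.89 ± 1.39 to 0.664 ± 0.214 CPM. In dividing cells, 8 were higher and 23 lower adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.617 with an estimated correlation). The 23 lower dividing-cell copies numbered 14 without SpIB2 day 2 replicate 1 and 14 without SpIB2 day 5 replicate 1. The 8 higher dividing-cell copies numbered 5 without SpIB2 day 5 replicate 2 and 2 with library totals. The dividing-cell list lost its call without SpIB2 day 2 replicate 1 or SpIB2 day 5 replicate 1 (camera adjusted p = 0.055 to 0.302). Anaerobic and low-oxygen genes were not called in SpIB2 (6 higher, 12 lower of 44; 5 and 9 adjusted over the list alone; camera adjusted p = 0.432). The 12 lower low-oxygen copies numbered 7 without SpIB2 day 2 replicate 2 and 7 without SpIB2 day 5 replicate 2.

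In SpIB2 edgeR called 2325 copies higher and 2508 lower on day 5 at an adjusted p under 0.05 (1849 and 1725 at least 2-fold). That is 4833 calls against 370 in SpIB1, but with each strain's 6 libraries fitted alone edgeR called 2591 (1491 higher, 1100 lower) against 2204, and limma voom with library weights per strain 2890 against 2267. Of calls at least 2-fold, the fits of each strain alone gave 2540 in SpIB2 and 842 in SpIB1, and without the 2 SpIB2 libraries that stood apart edgeR called 4089 and 1759 in all. The median absolute log2 change over all copies was 0.741 in SpIB2 and 0.318 in SpIB1, with a biological coefficient of variation of 0.369 and 0.191 when fitted alone. With library totals 26.6% of the SpIB2 calls were higher, against 48.1% with TMM, and the median copy shifted by -0.44.

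The last comparison tested whether the day effects differed between the strains. The median difference of the day effects was -1.95 on the log2 scale for cytosolic ribosomal proteins (219 of 249 lower and 0 higher; camera adjusted p = 1.54e-39, adjusted p = 0.497 with an estimated correlation). Counts for cytosolic ribosomal proteins adjusted over the list alone were 0 higher and 239 lower. The 219 lower ribosomal protein copies numbered 135 and 122 without SpIB1 day 2 replicate 1 or 3 and 131 without SpIB1 day 5 replicate 1. The general stress response had a median difference of 1.94 (38 of 65 higher and 1 lower; camera adjusted p = 9.63e-19, adjusted p = 0.289 with an estimated correlation), with 40 copies higher and 1 lower adjusted over the list alone. Amino acid synthesis was lower in 46 of 102 copies and higher in 5 (camera adjusted p = 1.86e-08, adjusted p = 0.289 with an estimated correlation). The 46 lower amino acid synthesis copies numbered 27 and 27 without SpIB1 day 2 replicate 1 or 3. Glycolysis and ethanol formation was lower in 22 of 44 and higher in 1 (camera adjusted p = 5.82e-07, adjusted p = 0.497 with an estimated correlation). The 22 lower glycolysis copies numbered 9 and 13 without SpIB1 day 2 replicate 1 or 2 and 11 without SpIB1 day 5 replicate 3. Higher were 20 of 43 copies for trehalose and glycogen, with 0 lower (camera adjusted p = 7.49e-10, adjusted p = 0.497 with an estimated correlation). Anaerobic and low-oxygen genes had 20 of 44 higher and 0 lower (camera adjusted p = 7.37e-12, adjusted p = 0.289 with an estimated correlation). The 20 higher low-oxygen copies numbered 13 with library totals. Adjusted over the list alone the copies higher and lower were 6 and 54, 2 and 25, 25 and 0, and 25 and 0 in this order.

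The day effect of the maltase copy MAL32_1 was 1.01 ± 0.37 in SpIB1, short of the threshold but called in 4 of 17 alternatives (edgeR, DESeq2 and limma adjusted p from 0.0089 to 0.466). It was -1.20 ± 0.37 in SpIB2, and the difference passed the test (log2 -2.20 ± 0.52, edgeR adjusted p = 0.0102). So did that of MAL32 summed over copies (-2.25 ± 0.48, edgeR adjusted p = 0.00689). The transporter copy MAL11_1 had a higher day effect in SpIB2 (1.28 ± 0.34, edgeR adjusted p = 0.016), and so had MAL11 summed over copies (1.48 ± 0.37, edgeR adjusted p = 0.013). The MAL11_1 call ended with library totals (edgeR, DESeq2 and limma adjusted p over the alternatives 0.00048 to 0.244). MAL31 summed did not pass the test (-0.52 ± 0.47, edgeR adjusted p = 0.411). The maltose list as a whole was not called (camera adjusted p = 0.224), with 9 copies higher and 5 lower of 40 (9 and 5 adjusted over the list alone). The 9 higher maltose copies numbered 4 (with 5 lower) and 4 (with 5 lower) without SpIB1 day 2 replicate 2 or 3, 4 (with 5 lower) without SpIB1 day 5 replicate 1, 5 without SpIB2 day 2 replicate 1 and 2 (with 6 lower) with library totals (list median -0.41 against 0.36). In all, edgeR called 1554 copies higher and 1265 lower at an adjusted p under 0.05 (1526 and 1195 at least 2-fold). Of the calls, 55.1% were higher with TMM and 19.5% with library totals, where the median copy shifted by -0.71. Leaving out SpIB1 day 5 replicate 2 gave 997 higher and 715 lower, day 2 replicate 3 gave 1012 and 602, and without SpIB1 day 2 replicate 1 or 2 or day 5 replicate 1 the copies lower were 711, 759 and 761. Across copies the day effects of the strains correlated weakly (Pearson r = 0.085, Spearman rho = 0.030); 29 copies rose in both strains and 132 fell in both, where independent lists would share 20.1 and 65.4.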

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

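In this part, 2 tests were chosen only after the result was seen: the use of fits of each strain alone to weigh the shared spread, and the removal of the 2 SpIB2 libraries that stood apart. Everything listed here drew attention because the day effect differed between the strains in edgeR's test of that difference (SpIB2 day effect minus SpIB1 day effect), which called 1554 copies higher and 1265 lower. Camera called 13 gene lists in the same contrast, 0 of them with an estimated correlation, and 72 of the 108 copies named for the pairwise comparisons or for this one were called, 44 higher and 28 lower.

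Among the called lists, the medians above 0 (log2) were 1.95 for trehalose and glycogen (camera adjusted p = 7.49e-10, adjusted p = 0.497 with an estimated correlation), 1.94 for the general stress response (camera adjusted p = 9.63e-19, adjusted p = 0.289 with an estimated correlation), 1.76 for anaerobic and low-oxygen genes (camera adjusted p = 7.37e-12, adjusted p = 0.289 with an estimated correlation) and 1.35 for gluconeogenesis and the glyoxylate cycle (18 of 50 higher; camera adjusted p = 1.42e-06, adjusted p = 0.407 with an estimated correlation). The 18 higher gluconeogenesis copies numbered 11 with library totals. Autophagy and vacuolar proteases had 0.89 (19 of 54 higher; camera adjusted p = 6.36e-05, adjusted p = 0.569 with an estimated correlation). The 19 higher autophagy copies numbered 11 without SpIB1 day 2 replicate 3, 9 without SpIB1 day 5 replicate 1 and 7 (with 5 lower) with library totals (list median 0.10 against 0.89). The TCA cycle and respiratory chain had 0.52, which turned to -0.31 with library totals (13 of 88 higher; camera adjusted p = 0.00519, adjusted p = 0.619 with an estimated correlation), and hexose transport and glucose sensing 0.26, which turned to -0.49 (13 of 51 higher; camera adjusted p = 0.0354, adjusted p = 0.619 with an estimated correlation). The 13 higher TCA cycle and respiratory copies numbered 6, 7 and 5 without SpIB1 day 2 replicate 1, 2 or 3, 5 and 6 without SpIB1 day 5 replicate 1 or 2, 8 without SpIB2 day 5 replicate 1 and 6 with library totals. The TCA cycle and respiratory list lost its call without SpIB2 day 5 replicate 1 (camera adjusted p = 0.0827). The 13 higher hexose transport copies numbered 8 without SpIB1 day 5 replicate 2 and 8 with library totals. The hexose transport list lost its call without SpIB1 day 2 replicate 1 or 2 or SpIB2 day 2 replicate 1 or SpIB2 day 5 replicate 1 (camera adjusted p = 0.0522 to 0.181). The medians below 0 were -1.95 for cytosolic ribosomal proteins (camera adjusted p = 1.54e-39, adjusted p = 0.497 with an estimated correlation), -1.45 for glycolysis and ethanol formation (camera adjusted p = 5.82e-07, adjusted p = 0.497 with an estimated correlation) and -1.03 for amino acid synthesis (camera adjusted p = 1.86e-08, adjusted p = 0.289 with an estimated correlation). Ribosome biogenesis had -1.04 (15 of 119 lower; camera adjusted p = 2.96e-06, adjusted p = 0.619 with an estimated correlation), dividing cells -0.87 (13 of 61 lower; camera adjusted p = 0.00221, adjusted p = 0.619 with an estimated correlation) and nitrogen catabolite repression -0.72 (28 of 80 lower; camera adjusted p = 1.88e-05, adjusted p = 0.544 with an estimated correlation). The 15 lower ribosome biogenesis copies numbered 8, 9 and 2 without SpIB1 day 2 replicate 1, 2 or 3, 3 and 9 without SpIB1 day 5 replicate 1 or 2, 32 and 6 without SpIB2 day 2 replicate 2 or 3, 7 and 41 without SpIB2 day 5 replicate 1 or 2, 6 (with 4 higher) without the 2 SpIB2 libraries that stood apart and 56 with library totals. The 13 lower dividing-cell copies numbered 8 and 5 without SpIB1 day 2 replicate 1 or 3, 8 and 7 without SpIB1 day 5 replicate 2 or 3, 8 without SpIB2 day 2 replicate 1, 20 without the 2 SpIB2 libraries that stood apart and 30 with library totals. The 28 lower nitrogen copies numbered 43 (with 2 higher) with library totals. Adjusted over the list alone, 23 copies were higher for gluconeogenesis, 23 for autophagy, 9 for the TCA cycle and 14 for hexose transport. Lower by the same adjustment were 0 for ribosome biogenesis, 13 for dividing cells and 31 for nitrogen genes.

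Among single copies with a higher day effect in SpIB2, the log2 differences were 7.31 for BOP2_2, 7.05 for SPG4_1, 5.13 for SPG5_2, 6.97 for HXT5_2 and 6.03 for HXT3_3. Stress and storage genes gave 6.62 for HSP30, 5.00 for SPI1_2, 4.66 and 2.66 for HSP12_2 and HSP12_1, 4.24 for GRE1, 2.03 for GRE3_2, 2.23 for YGP1_2, 3.93 for ATH1_2, 3.31 for TPS1_2, 2.21 for GAC1_2 and 2.01 for NTH2_2. Low-oxygen genes gave 5.20, 4.04 and 3.92 for PAU17_2, PAU17_1 and PAU5_2, 2.94 and 2.79 for TIR1_1 and TIR1_2 and 3.67 for SUT1_2. The meiosis genes SPO11_3 and IME2_2 stood at 5.10 and 4.62. Genes of respiration and carbon use gave 3.93 for NDE2_2, 1.70 for QCR8_1, 3.41 for CAT8_1, 2.93 for CRC1_1, 2.85 for ADY2, 2.00 for SFC1_1 and 1.77 for FBP1_2. Genes of nitrogen use, aroma and autophagy gave 3.08 for GDH3_1, 2.32 for UGA2_2, 2.64 for ARO10_2, 1.34 for BAT2_2, 2.45 for ATG39_2, 1.29 for ATG18_2 and 2.35 for CPS1_2. Maltose genes gave 2.15 and 1.82 for IMA2_6 and IMA2_9, 1.75 for MAL63 and 1.28 for MAL11_1, both without a call when libraries were scaled by their totals, and 1.80 and 1.53 for ZNF1_1 and MAL33_3, each without a call in 10 of 22 alternatives.

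Among single copies with a lower day effect in SpIB2, transporters gave -5.06 for OPT2, -4.60 for GAP1_1, -4.21 for DUR3_1, -4.20 for the dicarboxylic amino acid permease DIP5, -2.86 for GIT1_1 and -2.55 for UGA4_1. Nitrogen and amino acid genes gave -2.78 for the glutamine synthetase GLN1_2, -2.69 for CAR1_1, -1.80 for DAL80_1, -2.39 and -1.70 for ARO7_1 and ARO1_1, -1.71 for LYS21_1, -1.48 for HOM6_1 and -1.26 for MET17_1. Genes of glycolysis and aroma gave -2.21 for PDC6_1, -2.11 for PFK1_2, -1.98 for ENO2, -1.60 for PDC1_2 and -1.85 for ATF2_1. Ribosomal genes gave -2.51 for RPL8B_3, -2.08 for RPS0, -1.95 for RPL7B_1, -1.36 for MAK16_1 and -1.29 for SPB4_1, and the mitotic kinase CDC5_1 stood at -2.38. The maltase copies gave -2.20 for MAL32_1, -1.82 for MAL32_2 and -1.66 for MAL62, the last without a call when SpIB1 day 2 replicate 1 was left out (edgeR, DESeq2 and limma adjusted p over the alternatives 0.00197 to 0.0537).

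One pattern was weighed here, that edgeR called 4833 copies between days in SpIB2 and 370 in SpIB1, 13.06 times as many. Depth is argued against as the cause by a ratio of 13.37 with all libraries thinned to 5133175 reads, and scaling by a ratio of 16.24 with library totals. Without the 2 SpIB2 libraries that stood apart the ratio fell to 2.325, still above the bound of 1.5 set for that explanation as the whole cause, so those libraries may account for part of it. With each strain's 6 libraries fitted alone it was 1.176, so one estimate of the spread shared by both strains is a candidate explanation for most of the gap in calls at the adjusted p alone, while of calls at least 2-fold these fits still gave 842 in SpIB1 and 2540 in SpIB2. A difference between the strains themselves stays open and is not excluded by these counts, since the median absolute log2 change was 0.318 in SpIB1 and 0.741 in SpIB2.

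Other groupings of the libraries were compared with the real one. For the difference of the day effects 1 of 40 splits, the real one, gave as many calls (2819, against 1070 in the highest other split). The other splits mixed the libraries of both strains and both days. They cannot show what equal day effects would give, so no conclusion on chance is drawn from them. For the pairwise comparisons, 10 splits each are too few for a share under 0.05; the real counts were 3762 for the strains on day 2, 6015 on day 5, 370 for the days in SpIB1 and 4833 in SpIB2, and the highest other split gave 0 in each, so 1 split gave as many.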

How the results depend on the processing

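Chosen after the data were seen were the restored cells, the removal of the 2 SpIB2 libraries that stood apart, the sums per symbol and the library weights per strain. Of 167 copy results named in the text, 148 kept their direction and their side of the threshold in the alternatives run; over single values, 2915 did, 76 lost the call, 6 gained it and 1 reversed. That one was MAL31_2 between days in SpIB2, uncalled both ways, at -0.01408 with library totals. For called lists 573 values kept the call and 115 lost it; of 600 values of uncalled lists 52 turned direction, 0 of them with a call. Depth limits copies near the floor of 3 reads. Results per chromosome or parental genome were not run.

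Counts are given as copies higher and lower, and the cause was not tested unless stated. With library totals they were 1502 and 4863 between strains on day 5, 155 and 148 between days in SpIB1, 1311 higher between days in SpIB2, and 692 and 2857 for the difference of the day effects. DESeq2 gave 463 and 660 between days in SpIB1. Fits on only the 6 libraries compared gave 1070 and 1134 in SpIB1 and 1491 and 1100 in SpIB2. Without the 2 libraries that stood apart edgeR gave 766 and 993 in SpIB1. Library weights per strain in limma voom gave 988 and 1279 in SpIB1 and 1305 lower in SpIB2. Sums per symbol, with fewer units tested by construction, gave 925 and 809 between strains on day 2, 1758 and 1654 on day 5, 56 higher in SpIB1, 1378 and 1516 in SpIB2, and 978 and 769 for the difference. Camera with an estimated correlation called 0, 0, 1, 0 and 0 lists in the order of the comparisons, and fry 4 lists on day 2 between strains and 4 in SpIB1.

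Leaving out 1 library at a time gave 1257 to 2145 higher and 1077 to 1726 lower between strains on day 2, with the lowest of both without SpIB1 day 2 replicate 1, and 2626 to 3124 and 2411 to 2807 on day 5. In SpIB1 the ranges were 20 to 87 and 66 to 195, lowest without day 2 replicate 1 and day 5 replicate 2, and in SpIB2 1889 to 2389 and 1970 to 2411. For the difference of the day effects they were 997 to 1769 and 602 to 1492, lowest without SpIB1 day 5 replicate 2 and SpIB1 day 2 replicate 3. Lists called ranged from 7 to 10, 9 to 11, 10 to 15, 15 to 17 and 11 to 14.

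The replicate numbers did not pair the samples, since in no contrast did every same-numbered pair correlate above 0.1 in its deviations, and not every sample correlated best with its own number. With the replicate as a block edgeR gave 40 and 166 in SpIB1 and 801 lower for the difference, against 278 and 1265 lower without it. The other counts over all copies stayed within 1.5 times. Among list counts of 8 or more given in the text, the block moved by over 1.5 times ergosterol synthesis between strains on day 2 (8 lower to 4), nitrogen (12 higher to 4) and sulfate genes (10 lower to 5) in SpIB1, ribosome biogenesis in SpIB2 (38 lower to 22), and the TCA cycle (13 higher to 5), maltose (9 higher to 5) and ribosome biogenesis (15 lower to 6) lists in the difference. The camera call for dividing cells in SpIB1 ended with the block (camera adjusted p = 0.0585), and single calls lost were MAL31_2 on day 5, MAL33_2 and DUR3_1 in SpIB1, and MAL33_3 and ZNF1_1 in the difference.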

Other observations

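In this part, the tests on copies nearly unread in SpIB1 and on read shares were chosen only after the results were seen, the iron tests before. Shares of all reads in a library are on the library-total scale. In SpIB1 the maltase MAL32 summed over copies took 0.227 to 0.360% on day 2 and 0.534 to 0.844% on day 5. In SpIB2 it took 0.557 to 0.885% and 0.158 to 0.301%. The transporter MAL11 took 0.0122 to 0.0170% on day 2 in SpIB1 and 0.00381 to 0.00639% in SpIB2, and on day 5 0.0168 to 0.0229% and 0.00976 to 0.0126%. The strains' libraries did not overlap in these shares on either day (chance gives 10% for 3 against 3). On day 5 the TMM-scaled test of MAL11 found no difference at its threshold. With library totals the median copy then shifted by -0.75 (log2), so these MAL11 shares cannot tell a strain difference from that shift. MAL31, summed, took 0.108 to 0.172% in SpIB1 and 0.171 to 0.257% in SpIB2 on day 2, where the ranges overlapped.

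Beyond dividing cells on day 2, camera called no list of cell states or osmotic stress between the strains. The sporulation list was not called on day 2 (2 higher and 10 lower of 39; camera adjusted p = 0.221) or on day 5 (6 and 9; camera adjusted p = 0.777). Genes of mating-competent cells were not called either (5 and 4 of 23 on day 2, camera adjusted p = 0.995; 10 and 4 on day 5, camera adjusted p = 0.462). Nor were glycerol and osmotic response (1 and 6 of 27 on day 2, camera adjusted p = 0.216; 6 and 6 on day 5, camera adjusted p = 0.66) and glucose repression signalling (6 and 2 of 33 on day 2, camera adjusted p = 0.955; 10 and 7 on day 5, camera adjusted p = 0.62). Adjusted over the list alone, the copies higher and lower on day 2 were 2 and 10, 5 and 4, 0 and 5, and 6 and 2 in this order. On day 5 they were 5 and 8, 10 and 4, 6 and 6, and 10 and 7. Fry called mating genes higher on day 5 (fry adjusted p = 0.0043). With library totals the day 5 medians of the mating-competent and glucose repression lists turned negative, from 0.08 to -0.67 and from 0.43 to -0.33, and the copies higher and lower on day 5 numbered 4 and 5 for mating, 1 and 14 for osmotic and 7 and 12 for glucose repression genes, with 14 lower for sporulation. On day 2 mating genes then had 3 and 4, and 8 and 7 without the 2 SpIB2 libraries that stood apart. The 6 lower osmotic copies of day 2 numbered 3 without SpIB1 day 2 replicate 1 or 2 or SpIB2 day 2 replicate 1, and the 6 higher ones of day 5 numbered 3 without SpIB1 day 5 replicate 1 or 2.

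Reads were nearly absent in SpIB1 (at most 3 over 6 libraries) for 225 copies with a mean of at least 5 CPM in SpIB2, 187 with a symbol and 38 with a locus tag only, and 0 copies showed the reverse. Low depth is argued against, since a median of 1292 reads would be expected at the SpIB2 level. For 171 symbols with 1 partner copy, the partner was higher in SpIB1 by a median of 0.93 (95% interval 0.76 to 1.08, log2 of library-total CPM) against 0.45 for 3606 other symbols, at percentile 100 of 10000 random lists; reads counted on the partner and a second dose of the partner both predict this and cannot be told apart. Among locus tags, 31 neighbouring pairs were silent together where 1.09 would be expected (p = 1e-04 in 10000 permutations, the smallest they can give), so missing or replaced blocks of neighbouring genes in SpIB1 are a candidate explanation, if neighbouring tags lie side by side. The sum of both copies had a median of -0.07 against 0.27 for other symbols.

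The starvation list was called lower in SpIB2 on day 2 (camera adjusted p = 0.00155, adjusted p = 0.993 with an estimated correlation). On day 5 fry called it lower (fry adjusted p = 0.0222) where camera did not (camera adjusted p = 0.109). Summed over copies, 6 iron-responsive symbols picked because they were low (FTR1, FET3, SIT1, ARN1, FRE4 and TIS11) had a median log2 strain difference of -2.947 over both days and the highest single value was -1.70, which argues against reads moving between copies of a symbol. Of 13 further iron-responsive symbols, 7 were lower on each day and 0 and 1 higher (MRS4 on day 5), with medians of -0.84 and -0.92; camera gave p = 0.00122 on day 2 and p = 0.01409 on day 5, and 0.0142 and 0.0527 as p with an estimated correlation. A lower expression of iron-responsive genes in SpIB2 may therefore reach beyond the genes first seen on day 2, while for day 5 this stays open, since the p with an estimated correlation missed 0.05. Iron in the wort or in the cells was not measured here, and a genetic difference between the strains was not tested.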
